A study of Mus musculus with 35 samples.

How the data were processed

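The series holds 35 RNA sequencing libraries of microglia sorted from female mice that carried Tbk1 alleles flanked by loxP sites. Per the labels' protocols, tissue was Dounce homogenised, debris was removed on a Percoll gradient, viable cells positive for CD11b and CD45 were collected by flow cytometry, and libraries were made with the SMART-Seq v4 and Nextera XT kits. Between 10000 and 30000 cells were sorted per sample, and RNA from 2500 to 5000 of them was sequenced. The same protocols state that the RNA was too scarce for concentration and integrity to be measured in every sample. Mice without the Cx3cr1-Cre transgene are called WT here and mice with it KO, in which both Tbk1 alleles are deleted in cells that express Cx3cr1. Heterozygous mice mentioned in the design text were not analysed here. No group analysed carried Cre with intact Tbk1. Effects of the Cre transgene itself therefore cannot be told apart from loss of Tbk1 in any comparison of KO with WT.

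The deposited values are TPM, a length-normalised share of transcripts, which the authors made per library. Group means of their sum per library ran from 999946 to 999964 in the first table and from 999632 to 999735 in the other. FastQC, Trimmomatic, DRAGEN and Picard appear in the submitters' processing notes without versions, and which of them aligned or quantified the reads is not given in the sources used here. The first table, mapped to mm10 per the labels, has 28806 genes in 19 libraries, which are untreated spinal cord of both genotypes at 4 and 22 months. The other, mapped to mm39 per the labels, has 41482 genes in 26 libraries, which are lipopolysaccharide (LPS) treated spinal cord and brain of both genotypes plus the 10 untreated 4 month spinal cord libraries again. Gene symbols in both tables numbered 26038. No counts were given, so the depth of each library is unknown and no counting interval was computed. Tests were made within a table only. The correlation of genotype in LPS and untreated spinal cord took log2 changes from both tables, matched by gene symbol. The characteristics and design text give the LPS brain libraries an age of 4 months, whereas their titles say 22 months; the protocol text describes brains only, although spinal cord libraries exist.

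TPM were taken as log2(TPM + 1) and genes with a TPM of at least 1 in at least 4 libraries were kept, which left 15080 genes for the untreated libraries and 19404 for the others. Differences were tested with limma 3.58.1 in R 4.3.3, by a model with a mean per group, the mean-variance trend of the residuals (trend = TRUE), and Benjamini-Hochberg adjustment at 0.05. The model of the untreated libraries held 19 of them, and that of the LPS libraries held 16. TPM are given as mean ± SD with the number of libraries n, and log2 changes as the estimate ± SE. Libraries were treated as separate mice, and library numbers are those of the labels. Whether LPS spinal cord and brain libraries of the same number came from the same mouse is not given in the sources used here. Per-gene levels and library measures were also compared with 2-sided exact permutation tests, adjusted over the 15 library measures of a comparison where these are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

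Gene lists were fixed before the data were examined, as were the groups, the comparisons between genotypes, ages and tissues, the threshold and most alternatives. The 30 lists cover microglial states (homeostatic, disease-associated, type I interferon-stimulated, MHC class I, MHC class II, inflammatory cytokines and NF-kB targets), pathways (TBK1 pathway, autophagy, lysosome, complement and phagocytic receptors, cell death and inflammasome, cell cycle, cholesterol synthesis, lipid efflux and lipid droplets, glycolysis, respiratory chain, TGF-beta signalling), RNA and handling quality (ex vivo activation and immediate early genes, mitochondrially encoded genes, ribosomal proteins) and other cells (border macrophages, monocytes, neutrophils, T and NK cells, B cells, oligodendrocytes and myelin). Lists of neurons, astrocytes, erythrocytes and endothelial cells with pericytes had fewer than 5 tested members and were not tested, nor were B cells in the LPS model, which left 26 lists for untreated libraries and 25 for the LPS libraries. Lists were tested with camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data and with fry. Adjusted p are over the lists tested in a comparison.

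Genes were named by rule: adjusted p under 0.05, a mean of at least 5 TPM in a group, no overlap between the libraries of the groups, and then the 10 largest changes in each direction, or 5 for ageing in KO and for interactions. Predicted genes and pseudogenes were passed over. Where fewer than 3 genes qualified in a direction, the 3 with the smallest unadjusted p were named without being called changed. Up to 4 members of each list and a fixed set around Tbk1 were added to these. On simulated data with the groups' own spread and 100 genes shifted by each size, 92% of shifts of 1 and 99% of shifts of 2 on the log2 scale were recovered for genotype at 4 months with 3.95% false calls. The corresponding values were 94%, 99% and 3.06% at 22 months, 71%, 96% and 3.12% in LPS spinal cord, and 88%, 99% and 6.17% for LPS against untreated WT. The shifted genes lay above about 5 TPM, noise was independent between genes, and 30 more genes were shifted. These shares therefore do not bound what was missed in the measured data. In measured LPS spinal cord Tbk1 itself, at -1.86, was not called.

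Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at TPM 5, quantile normalization, centring each library on its median, a fit of the compared groups alone, library weights, the robust option, the replicate number as a block, and leaving out each library. Chosen only after the data had been seen were the comparisons of LPS with untreated spinal cord and their interaction with genotype, a model of the 18 spinal cord libraries of the mm39 table, fits without the pair of brain libraries whose Tbk1 goes against their labels, a fit without the 22 month KO library with the highest neutrophil markers, TPM rescaled over protein-coding genes, counts of called genes with the young WT libraries split between genotype and age, and the mm39 mapping of the untreated libraries beside mm10 with the same groups alone. No library was regrouped. Coordinates are from the GRCm38.p6 annotation, the assembly of mm10.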

Results

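TBK1 is a kinase that relays nucleic acid sensing to interferon genes and also acts in NF-kB signalling and selective autophagy. The libraries measured its loss from sorted mouse microglia, as TPM. Untreated spinal cord at 4 months gave 5 WT and 5 KO libraries, and untreated spinal cord at 22 months gave 5 WT and 4 KO. LPS treated mice gave 4 WT and 4 KO libraries of spinal cord, and the same numbers of brain. Pairs of libraries within a group correlated at 0.975 to 0.988, and no pair was duplicated.

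The first question was how far Tbk1 was lost. At 4 months Tbk1 was 11.1 ± 1.95 TPM (n = 5) in KO and 45.1 ± 4.68 (n = 5) in WT, or 24.5% of the WT level, with an exact permutation p of 0.00794, the smallest the groups allow. At 22 months it was 8.61 ± 1.52 (n = 4) against 33.7 ± 3.66 (n = 5), or 25.6%, with the same exact p. In LPS spinal cord it was 7.80 ± 2.44 (n = 4) against 30.3 ± 4.93 (n = 4), or 25.8%, with an exact p of 0.0286, again the smallest possible. In LPS brain the KO mean was 24.2 ± 20.6 (n = 4) and the WT mean 40.2 ± 15.6 (n = 4), with an exact p of 0.2. The brain library labelled WT 2 had 18.6 TPM where the other WT had 41.9 to 55.7, and that labelled KO 2 had 55.0 where the other KO had 11.5 to 16.2. Cx3cr1, whose promoter drives the Cre, was 4782 ± 70.1 TPM in KO and 5054 ± 133 in WT at 4 months (exact p = 0.00794, limma adjusted p = 0.813). In mm10, Tbk1 lies on chromosome 10 at 121546455 to 121586794 and Cx3cr1 on chromosome 9 at 120048683 to 120068296.

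**Figure D1:**
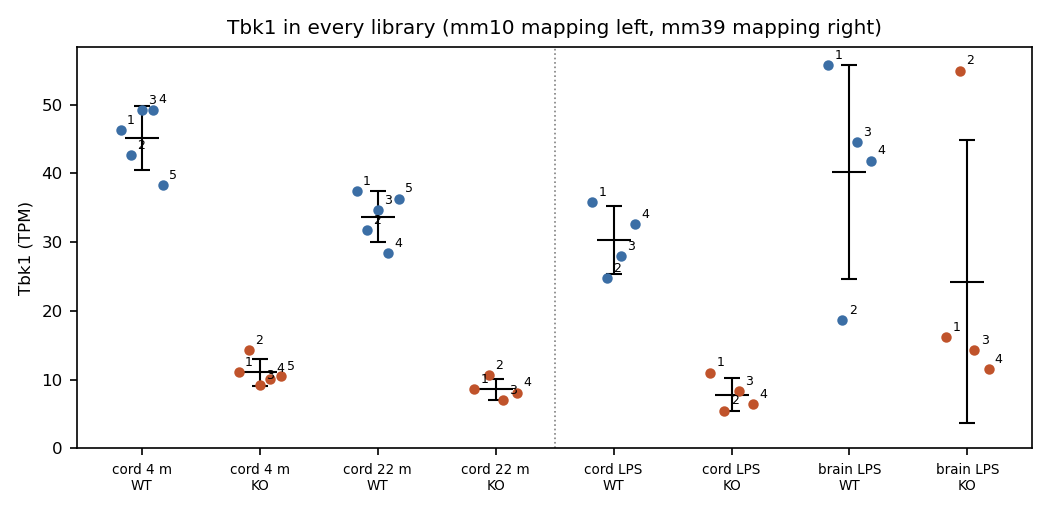
Tbk1 in TPM in each library of the 8 groups, with the mean and SD, from the mm10 table on the left and the mm39 table on the right. KO libraries lie below WT libraries in every group except LPS brain, where the libraries labelled WT 2 (18.6) and KO 2 (55.0) lie with the other genotype.

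The comparison of KO with WT at 4 months asked how young KO and WT microglia differ. Chemokines, the adhesion molecule Vcam1 and the nuclear receptor Rxrg were among the largest increases. Cxcl13, which draws B cells, rose by 4.82 ± 0.35 log2 units (adjusted p = 1.06e-08), to 66.4 ± 24.9 TPM (n = 5) from 1.81 ± 2.14 (n = 5). Cxcl10, an interferon-induced chemokine, rose by 3.23 ± 0.35 to 71.0 ± 27.9 from 6.87 ± 3.93, and Ccl5 by 2.94 ± 0.32 to 68.0 ± 11.8 from 8.21 ± 2.70. Vcam1 rose by 2.94 ± 0.13 (adjusted p = 3.57e-12), to 83.4 ± 9.40 from 10.0 ± 1.70, and the adhesion molecule Madcam1 by 2.07 ± 0.32 to 7.17 ± 2.81 from 0.966 ± 0.779. Rxrg rose by 2.80 ± 0.19 to 20.4 ± 1.63 from 2.25 ± 1.12, the collagen crosslinking enzyme Lox by 2.28 ± 0.24, and the activation antigen Cd69 by 2.20 ± 0.31. The cytokine receptor chain Il2rg rose by 1.88 ± 0.08 to 150.2 ± 11.8 from 40.3 ± 5.46. The receptor kinase Axl, which recognises dying cells, rose by 1.43 ± 0.10 to 204 ± 18.3 from 76.1 ± 14.9. In all, limma called 119 genes up and 26 down of 15080, of which 11 were predicted or unnamed.

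Of the 36 inflammatory cytokines and NF-kB targets, 12 rose and 1 fell at 4 months, and 18 rose and 2 fell adjusted over the list alone. The list's median was 0.37, and its adjusted p was 1.4e-05 with an estimated correlation. Ccl2 rose by 1.60 ± 0.19 to 30.3 ± 5.98 TPM, Cd40 by 1.66, and Cxcl16 by 1.00 ± 0.07 to 207 ± 17.5. The inhibitors and subunits of NF-kB rose too, with Tnip1 at 0.72, Nfkb2 at 0.66, Relb at 0.65 and Nfkbia at 0.61, and Ebi3 rose by 0.59 ± 0.08. Ccl3 went the other way and fell by 0.97 ± 0.16 to 47.0 ± 9.31 from 92.3 ± 14.6, while Tnf was unchanged at -0.03. Il1b rose by 1.17 ± 0.24 (adjusted p = 0.0136), to 15.5 ± 4.22 from 6.54 ± 2.66, and lost its call without the 4 month library KO 5 (0.054) and in the mm39 mapping (0.16). In the MHC class I list of 20 genes, which carry peptides to CD8 T cells, 8 rose (11 adjusted over the list alone; adjusted p = 0.00123 with an estimated correlation). H2-K1 rose by 0.92 ± 0.08 to 1563 ± 151 TPM from 824 ± 80.7, H2-D1 by 0.79 ± 0.08 to 2935 ± 313 from 1694 ± 100.4, and B2m by 0.44. H2-Q7 rose by 2.27 ± 0.16 and H2-Q6 by 2.01 ± 0.17, although H2-Q genes share sequence and reads may be exchanged between them. Of 9 MHC class II genes, Cd74 (1.20 ± 0.16, to 460.3 ± 63.6 from 204 ± 53.7) and H2-Oa (0.64 ± 0.10) rose, the same count adjusted over the list alone, and the list was not called with an estimated correlation (0.101).

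Of 52 interferon-stimulated genes at 4 months, 46 had a positive change, with a median of 0.34, yet only Cxcl10, Ccl12 and Gbp2 were called, and 6 adjusted over the list alone. Cxcl10 and Ccl12 (1.49 ± 0.14, to 413 ± 85.8 TPM from 145 ± 25.4) are chemokines that other signals also induce. Gbp2 rose by 0.89 ± 0.21 (adjusted p = 0.0457) and lost its call without any of 9 libraries (0.069 to 0.153). The list's adjusted p was 0.160 with an estimated correlation, and Irf7 was at 0.96 (adjusted p = 0.375). In the mm39 mapping 14 were called adjusted over the list alone. Homeostatic genes went down together. Of 24, 4 fell (10 adjusted over the list alone; median -0.16; adjusted p = 0.0139 with an estimated correlation). They were Fcrls, which fell by 0.62 ± 0.06 to 1131 ± 61.2 TPM from 1744 ± 87.1, Crybb1 (-0.60 ± 0.10), the fructose carrier Slc2a5 (-0.50 ± 0.06, to 659.9 ± 53.4 from 936 ± 70.7) and Gpr34 (-0.18 ± 0.04), which lost its call without any of 7 libraries (0.0594 to 0.0904). P2ry12 was at -0.22 (adjusted p = 0.0583), and Tmem119 at 0.07 was unchanged. Outside that list the protease Htra3 fell by 0.86 ± 0.12, Masp1 by 0.84 ± 0.17, S1pr1 by 0.58 ± 0.11, Ppdpf by 0.53 ± 0.09, and the Axl ligand Gas6 by 0.60 ± 0.11 to 95.5 ± 9.88 from 144 ± 7.21. Afap1l1 fell by 0.69 ± 0.15 and lost its call without any of 7 libraries (0.0537 to 0.0700). In the mm39 mapping Masp1 (0.0692), S1pr1 (0.0506) and Gpr34 (0.137) were not called, nor were Masp1 (0.0543) and Gpr34 (0.0652) in mm10 with the same groups fitted alone.

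Disease-associated genes had no common direction at 4 months. Of 34, 3 rose and 1 fell (5 and 3 adjusted over the list alone), with Axl and Itgax (1.03 ± 0.16) up and Ccl6 down (-0.45 ± 0.09). Apoe was at -0.54 (adjusted p = 0.843). The list's median of 0.01, mean of -0.01 and upward test (0.309) differed in sign. In the complement and phagocytic receptor list of 25, 3 rose and 1 fell (6 and 1 adjusted over the list alone), and its adjusted p went from 0.00757 to 0.118 with an estimated correlation. C3 in it rose to 12.3 ± 2.04 from 4.61 ± 4.39 (adjusted p = 0.0128), but lost its call without WT 5 (0.0543), and Fcgr4 (0.45) lost it without WT 2, WT 4, KO 1, KO 3 or KO 5 (0.0637 to 0.0749). In the mm39 mapping Itgax (0.0616), Ccl6 (0.0612), C3 (0.162) and Fcgr4 (0.0843) were not called, nor were C3 (0.0956) and Fcgr4 (0.0662) in mm10 with the same groups fitted alone. Of 23 TBK1 pathway genes, Tank, which binds TBK1, rose by 0.91 ± 0.13 to 40.0 ± 7.24 from 20.8 ± 3.46, and Tbk1 itself fell by 1.94 ± 0.13. Irf3, Ripk1, Optn, Sqstm1 and Ikbke changed by no more than 0.09 in either direction and none was called. Ctsh (0.22 ± 0.04) was the only lysosome gene called of 38, and was not called after quantile normalization (adjusted p = 0.100) or in the mm39 or mm10 mapping with these groups alone (0.0534 and 0.0539). The adjusted p of that list went from 0.0119 to 0.571 with an estimated correlation, as that of the 34 cell cycle genes went from 0.0349 to 0.761. All 15 mitochondrially encoded genes had positive changes (median 0.23) with 0 called, 2 adjusted over the list alone (0.294 with an estimated correlation). Their share of TPM was 2.41% in KO and 1.98% in WT (exact p = 0.0397, adjusted p = 0.238). In the list of 11 T and NK cell genes only Ccl5, a chemokine that microglia also make, was called (adjusted p = 0.160 with an estimated correlation). The other members added up to 50.7 TPM in KO and 36.9 in WT (exact p = 0.0476, adjusted p = 0.238). Border macrophage genes, 1 of 11 of them called (Gas6), added up to 111 TPM in KO and 160.4 in WT (exact p = 0.00794, adjusted p = 0.119). Cd22 (0.78 ± 0.15), a microglial receptor too, was the only B cell gene called of 6, and was not called in the mm39 mapping (0.0578). The other 16 lists were not called at 4 months.

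The same comparison at 22 months asked whether the response lasts into old age. Cxcl13 rose by 4.22 ± 0.37 (adjusted p = 8.82e-07), to 636 ± 138 TPM (n = 4) from 33.4 ± 7.79 (n = 5). Vcam1 rose by 1.68 ± 0.14 to 202 ± 42.0 from 61.9 ± 9.42, Rxrg by 1.25 ± 0.20 to 84.6 ± 9.46 from 35.2 ± 5.72, and Ccl5 by 1.96 ± 0.34. The lipase Aoah, which inactivates LPS, rose by 1.89 ± 0.31, Ip6k3 by 2.15 ± 0.29, H2-M2 by 2.01 ± 0.27 and Ehd1 by 1.63 ± 0.30. The neutrophil chemokine Cxcl2 (2.39 ± 0.43, to 10.6 ± 11.7 from 0.703 ± 0.836) and the itaconate enzyme Acod1 (2.09 ± 0.39) rose at 22 months but had adjusted p of 0.995 and 0.986 at 4 months. Fcrls fell by 0.67 ± 0.06 (adjusted p = 1.22e-06) to 797 ± 43.1 from 1267 ± 103, and Pear1 fell by 1.12 ± 0.12 to 9.21 ± 0.919 from 21.2 ± 2.23. The inhibitory receptor Fcgr2b fell by 0.39 ± 0.06, Ccl6 by 0.62 ± 0.09, Slc2a5 by 0.42 ± 0.06, Upk1b by 0.71 ± 0.12, Khdrbs3 by 1.04 ± 0.19, Chchd6 by 0.98 ± 0.16 and Mpv17l by 1.28 ± 0.20. limma called 49 genes up and 31 down. Of these, 27 had risen and 10 had fallen at 4 months too, and 90.0% had the same sign there. Across all genes the log2 changes at both ages correlated at 0.191, and genes are not independent replicates.

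Several calls at 22 months were lost when a library was left out or the pseudocount changed. Leaving out KO 2 ended those of Ptprcap (1.90 ± 0.36; 0.0605), Htra3 (-0.66 ± 0.12; 0.0594), Gas6 (-0.58 ± 0.11; 0.0691) and Mrc2 (-1.16 ± 0.22; 0.0594), the last also lost without KO 1 (0.0598). H2-Q6 (0.96 ± 0.18) lost its call without KO 3 (0.0506). Mcemp1 (1.66 ± 0.37) lost its call without any of 8 libraries (0.0528 to 0.201), and Mettl15 (-0.83 ± 0.17) without any of 7 (0.0601 to 0.0897). With a pseudocount of 0.1, H2-M2 (0.0637), Cxcl2 (0.0843), Acod1 (0.321), Ptprcap (0.0609), Cd2 (0.153) and Mcemp1 (0.223) were not called. Leaving out any library kept the count between 54 and 89.

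Of the 36 NF-kB targets and cytokines, 10 rose at 22 months (18 up and 1 down adjusted over the list alone; median 0.34; adjusted p = 1.3e-05 with an estimated correlation). Il12b rose by 2.20, Cd40 by 1.59, Nfkbia by 0.56 ± 0.09 to 401 ± 58.0 TPM from 269.9 ± 13.7, and Cxcl16 by 0.44 ± 0.08. Il1b was at 0.34 (adjusted p = 0.764) and Tnf at 0.37 (0.768). Of 24 homeostatic genes, 3 fell (9 adjusted over the list alone; adjusted p = 0.0301 with an estimated correlation), among them Gpr34 (-0.29 ± 0.04, to 2288 ± 85.0 from 2807 ± 99.2). MHC class I kept 3 increases of 20 (4 adjusted over the list alone), with H2-K1 at 0.44 ± 0.08 and H2-Q7 at 0.96 ± 0.17. The list was no longer called with an estimated correlation (0.201). No interferon-stimulated gene was called, 2 adjusted over the list alone, and the list's adjusted p went from 0.00396 to 0.611. Cxcl10 was at 1.47 (adjusted p = 0.103; 105 ± 31.1 against 37.9 ± 12.8 TPM) and Irf7 at 0.26. The disease-associated list leaned down, with Ccl6 the only member called (1 up and 5 down adjusted over the list alone), and its adjusted p of 0.0120 became 0.533 with an estimated correlation. Lysosome genes went the same way (0.00505 and 0.432).

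Markers of other leukocytes had higher means in KO at 22 months, with adjusted p above the threshold for their summed TPM. In the T and NK cell list of 11, Cd2 (1.63 ± 0.33) and Ccl5 rose, 9 rose adjusted over the list alone, and the adjusted p was 0.00551 with an estimated correlation. Cd2 lost its call without WT 1 (0.0588), WT 2 (0.0526), WT 4 (0.0536), KO 2 (0.0961) or KO 3 (0.0781). Without Ccl5 the list's members added up to 101 ± 38.9 TPM (n = 4) in KO and 30.2 ± 19.3 (n = 5) in WT (exact p = 0.0238, adjusted p = 0.198). Neutrophil genes added up to 12847 ± 10523 against 3608 ± 5304 (exact p = 0.0397, adjusted p = 0.198) and monocyte genes to 1193 ± 897 against 414 ± 504 (exact p = 0.0794, adjusted p = 0.298). None of the 14 neutrophil genes (median 2.26) or the 13 monocyte genes (median 1.14) was called, and 1 in each adjusted over the list alone. The adjusted p with an estimated correlation were 0.388 and 0.270. Cell cycle genes (0 called, median 0.24, 0.394) and respiratory chain genes (0 called, median 0.09, 0.388) also lost their list calls. Median, mean and test differed in sign at 22 months for the TBK1 pathway, complement, cell death, lipid efflux, TGF-beta, ribosomal, B cell and myelin lists, none of them called, and at 4 months for cell death, cholesterol synthesis and border macrophages.

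**Figure D2:**
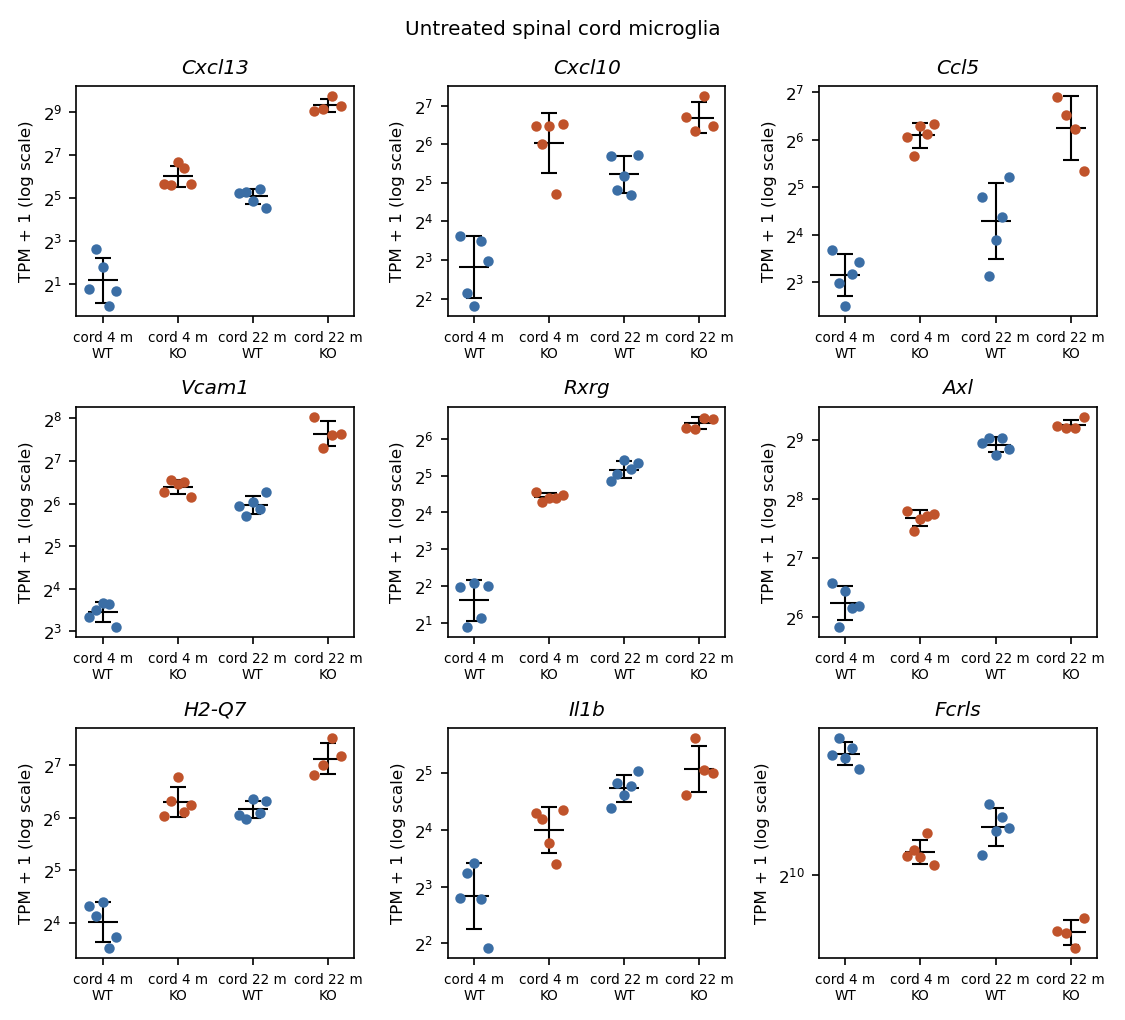
TPM + 1 on a log axis of 9 genes in each untreated spinal cord library, with the mean and SD of the 4 groups. Cxcl13 goes from 1.81 in WT to 66.4 in KO at 4 months and from 33.4 to 636 at 22 months. For Axl the ratio of KO to WT is larger at 4 months (204 and 76.1) than at 22 months (608 and 484).

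An interaction test asked whether the genotype difference itself changed with age, and 7 genes passed. As a log2 ratio of KO to WT, the genotype difference shrank for Axl (-1.10 ± 0.15, adjusted p = 0.00283). Axl was 204 TPM in KO and 76.1 in WT at 4 months but 608 ± 36.9 and 484 ± 41.4 at 22 months. The ratio shrank also for Il2rg (-1.05 ± 0.12, adjusted p = 1.66e-04, with 306 ± 3.88 and 172 ± 10.3 TPM at 22 months), Vcam1 (-1.26 ± 0.19), Rxrg (-1.55 ± 0.28, adjusted p = 0.0387) and H2-Q7 (-1.30 ± 0.24, adjusted p = 0.0452). In TPM the gap between the means was no smaller at 22 months for Il2rg, Vcam1, Rxrg and H2-Q7, whose WT means were higher at that age. Pear1 (-0.95 ± 0.16) gained a decrease, and Pilra (0.74 ± 0.13, adjusted p = 0.0290) gained an increase, to 128 ± 8.46 at 22 months. Rxrg and H2-Q7 each lost the call without any of 14 libraries (0.0508 to 0.149 and 0.0508 to 0.164), Pilra without any of 12 (0.0508 to 0.0791) and Pear1 without any of 11 (0.0508 to 0.104), whereas Vcam1, Axl and Il2rg kept it without each library left out. The count fell to 3 without 4 month KO 3, 4 month KO 5, 22 month WT 3, 22 month WT 4 or 22 month KO 2, and to 4 without 4 month WT 4, 4 month WT 5, 22 month WT 2 or 22 month KO 1. Of the MHC class I genes 7 were lower adjusted over the list alone, and the list had an adjusted p of 0.0694 with an estimated correlation. H2-M2 (1.58, adjusted p = 0.229) and Ganc (0.82, 0.129) did not pass, and for other genes called at a single age a difference between ages was not shown. After quantile normalization 0 rose and 6 fell, and after median centring 0 and 3.

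Ageing in WT microglia, from 4 to 22 months, is the reference for an aged-like state. Differences in batch or handling between young and old mice of either genotype were not tested and cannot be told apart from age here. Spp1 rose by 5.10 ± 0.44 (adjusted p = 2.68e-08), to 1719.7 ± 377 TPM (n = 5) from 60.8 ± 43.4 (n = 5), Gpnmb by 5.21 ± 0.28 to 44.8 ± 24.5 from 0.142 ± 0.159, and Apoe by 3.06 ± 0.38 to 6186 ± 2693 from 718 ± 252. Mmp12, Igf1, Cxcl14, Rab7b, Fabp5, Ch25h, Cxcl13 and Rxrg were the other large increases. Ch25h was at 212 ± 34.2 from 16.3 ± 3.92, and Igf1 at 25.0 ± 7.02 from 0.660 ± 0.488, and Cxcl13 rose by 3.89 ± 0.35 and Rxrg by 3.54 ± 0.19. Axl rose by 2.67 ± 0.10 (adjusted p = 1.75e-13), Lpl by 2.66 ± 0.18, Clec7a by 2.54 ± 0.11 to 572 ± 60.5 from 97.8 ± 14.4, Cst7 by 3.16 ± 0.17 and Ccl3 by 2.66 ± 0.16. Of 34 disease-associated genes 33 rose, 33 also adjusted over the list alone (median 2.05; adjusted p = 0.00031 with an estimated correlation). Of 24 homeostatic genes 22 fell (median -0.50; 0.00112). Among them were P2ry12 at 3399 ± 193 from 6568 ± 506, Tmem119 at 4365 ± 173 from 6184 ± 146, Csf1r (-0.46 ± 0.04) and Cst3 (-0.70 ± 0.07). Trem2 was unchanged (0.08, adjusted p = 0.318). The largest decreases were of Gpr165 (-2.51 ± 0.18), the protease Mmp28 (-2.16 ± 0.27), the adhesion molecule Pecam1 (-1.89 ± 0.14, to 4.08 ± 0.721 from 17.9 ± 3.06), Nrarp (-1.66 ± 0.28), Ccr1 (-1.61 ± 0.31), Mycl (-1.60 ± 0.16), Tmem204 (-1.55 ± 0.15), Tmem44 (-1.52 ± 0.21) and Nid2 (-1.47 ± 0.14). Fmr1nb (-1.69 ± 0.58) lost its call without any of 7 libraries (0.0685 to 0.134). limma called 1326 genes up and 1594 down, 395 of them predicted or unnamed. Median centring moved the share that rose from 45.4% to 62.6%.

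Inflammatory genes rose with age in WT as well. Of 36 NF-kB targets and cytokines 18 rose and 2 fell (19 and 3 adjusted over the list alone; 0.00096 with an estimated correlation). Ccl4 was at 899.9 ± 242 from 109 ± 32.2 TPM, and Ccl2 rose by 2.50 ± 0.19, Il1b by 1.90 ± 0.24 to 25.9 ± 4.46 from 6.54 ± 2.66, and Tnf by 1.43 ± 0.27. MHC class I (14 of 20; 0.0113) and class II (4 of 9; 0.0124) rose, with Cd74 at 855 ± 156 from 204 ± 53.7 and H2-Aa at 102 ± 37.2 from 19.4 ± 12.1. Of 52 interferon-stimulated genes 27 rose and 1 fell (32 and 1 adjusted over the list alone), among them Cxcl10 (2.41 ± 0.35), Ifi27l2a (2.05 ± 0.18) and Oas1a (1.32). The list was not called with an estimated correlation (0.114), and Irf7 (1.18 ± 0.34) lost its call without 22 month WT 1 (0.0536) or WT 5 (0.0587). Called with an estimated correlation were also lipid efflux (12 up and 3 down of 23; 0.00112), complement receptors (12 and 5 of 25; 0.00570), and glycolysis (12 of 19; 0.0113) with Pkm up by 1.12 ± 0.08. So were lysosome (21 and 3 of 38; 0.0269) with Ctsb at 6921 ± 657 from 4303 ± 116, and the respiratory chain (15 of 34; 0.0194) with Cox4i1 up by 0.57 ± 0.08. Ribosomal protein genes rose in 47 of 50 with 1 down (0.0113), Rpl32 to 772 ± 70.4 from 429 ± 45.4. The ribosomal share of TPM went from 1.51% to 2.25% and Malat1 TPM from 13045 ± 674 to 9591 ± 1383 (exact p = 0.00794 and adjusted p = 0.0298 for both). Cell cycle (13 of 34; 0.0780), cholesterol synthesis (7 of 21; 0.0822), monocyte (4 of 13, 9 adjusted over the list alone; 0.166), border macrophage (2 up and 1 down of 11; 0.166) and TGF-beta genes (6 down of 15, with Smad3 at -0.52 and Tgfbr1 at -0.42; 0.157) did not keep a list call. The same was true of 15 mitochondrially encoded genes (1 up, 0 adjusted over the list alone; 0.485) and 14 neutrophil genes (0 called; 0.485). Autophagy (4 up and 6 down of 36; 0.269), the TBK1 pathway (5 and 4 of 23; median -0.14, mean 0.06; 0.987) and cell death (4 and 5 of 26; median -0.03, mean 0.03; 0.974) were not called. Nor were immediate early genes (6 and 5 of 26, with Egr1 up by 1.94; median -0.04, mean 0.25; 0.207), T and NK cells (2 and 1 of 11; 0.348), B cells (1 and 3 of 6; 0.502) and myelin (2 of 7; 0.502). Tbk1 itself fell by 0.41 ± 0.13 with age, and lost the call without 4 month WT 3 (0.0617) or WT 4 (0.0619), or 22 month WT 2 (0.0568) or WT 4 (0.0735).

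Setting genotype beside age asked whether young KO microglia look aged. Of the 119 genes that rose in KO at 4 months 97 also rose with age in WT, against 10.5 for independent lists, and of the 26 that fell 12 also fell with age, against 2.75. Both comparisons use the same 5 young WT libraries, so chance in those libraries moves both alike. Across all genes the log2 changes correlated at 0.374, below the 0.502 (SD 0.0129) of simulated data with only the shared libraries, where the covariance was 0.0283 and the measured one 0.0490. With the young WT libraries split between the comparisons the correlation was 0.108 (0.0319 to 0.165 over 20 splits), again across genes that are not independent replicates. Tested on those splits, a check chosen after the data were seen, 73.2 genes on average rose in KO and 53.0 of them with age too, against 4.64 for independent lists, and 12.3 fell and 5.20 of them with age too, against 0.762. Cxcl13, Cxcl10, Axl, Cd74, H2-K1 and Il1b rose in both, and Fcrls and Slc2a5 fell in both. Ccl3 went opposite ways, falling by 0.97 in young KO and rising by 2.66 with age, and Apoe, P2ry12 and Tmem119, large changes of ageing, were not called in young KO.

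**Figure D3:**
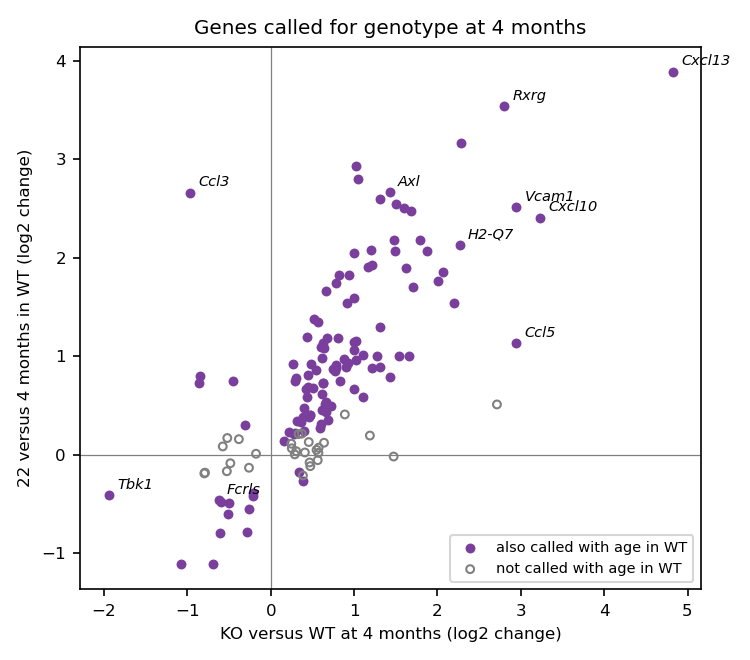
Log2 change in KO against WT at 4 months (x axis) and from 4 to 22 months in WT (y axis) for the 145 genes called in KO, filled where age was called too. Of these genes 89.0% have the same sign in both, and 87.0% of called genes do with the young WT libraries split. Simulated unchanged groups that share their controls give 95.1% over as many genes with the smallest p. In those simulations 0 genes were called in both with the same sign, whereas the 145 measured genes were called in KO. The 95.1% is therefore over genes picked from noise and is not an exact reference for the measured ones. The 89.0% with shared controls still shows no common change by itself.

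Ageing in KO microglia went much the same way. Spp1 rose by 6.02 ± 0.47 (adjusted p = 9.00e-09), to 1442 ± 347 TPM (n = 4) from 27.3 ± 26.5 (n = 5), Gpnmb by 5.48 ± 0.30, Mmp12 by 4.95 ± 0.43, Apoe by 3.21 ± 0.40 and Ccl3 by 3.20 ± 0.17. P2ry12 fell by 0.95 ± 0.06 to 2921 ± 145 from 5648 ± 242, Gpr165 by 2.60 ± 0.19, Pecam1 by 1.97 ± 0.15, Adtrp by 1.70 ± 0.26, Il7r by 1.69 ± 0.15 and the histone gene H4f16 by 1.64 ± 0.26. Disease-associated genes rose in 31 of 34 (0.00090 with an estimated correlation) and homeostatic genes fell in 23 of 24 (0.00149). Lipid efflux (14 up and 3 down; 0.00090), NF-kB targets (17 and 2; 0.00090), the respiratory chain (20 up; 0.00845), glycolysis (13 and 1) and ribosomal genes (47 up; 0.0194) were again called. Interferon-stimulated genes (15 and 2 of 52; 0.285), MHC class I (7 up; 0.125), MHC class II (4 and 1; 0.0596), cell cycle (13 up; 0.0596) and lysosome genes (12 and 6; 0.225) were not. Cxcl10 (0.66, adjusted p = 0.228) and Irf7 (0.48, 0.377) had no call, although only the genes of the interaction test are shown to differ from WT. Among markers of other leukocytes 13 of 13 monocyte genes rose (0.0596 with an estimated correlation), 6 of 14 neutrophil genes (13 adjusted over the list alone; 0.225) and 5 up and 1 down of 11 T and NK genes (0.125). The monocyte genes added up to 1193 TPM against 130.4 (exact p = 0.0159, adjusted p = 0.0476) and the neutrophil genes to 12847 against 1867 (exact p = 0.0397, adjusted p = 0.0992). The T and NK genes without Ccl5 added up to 101 TPM against 50.7 (exact p = 0.0159, adjusted p = 0.0476). Malat1 went from 13334 to 9107 TPM and the ribosomal share from 1.56% to 2.22% (adjusted p = 0.0397 for both). Among them Chil3 (4.58 ± 1.37) lost its call without 4 month KO 1 (0.053) or KO 3 (0.0506), or 22 month KO 1 (0.0522) or KO 2 (0.0608), and the neutrophil gene Camp (4.67 ± 1.58) without any of 7 libraries (0.0508 to 0.110). limma called 1520 genes up and 1879 down, 477 of them predicted or unnamed. Median centring moved the share that rose from 44.7% to 63.6%.

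LPS, a bacterial ligand of Toll-like receptor 4, is a strong inducer of interferon genes in which TBK1 takes part. In LPS treated spinal cord, the KO means of Cxcl10, Irf7 and Ccl4 were below those of WT and that of Cxcl13 was above, but no gene passed in the 16 library fit. Cxcl10 was 22.3 ± 21.8 TPM in KO (n = 4) and 232 ± 142 in WT (n = 4), a change of -3.49 (limma adjusted p = 0.220), Irf7 29.4 ± 7.08 against 121 ± 30.6 (0.220) and Ccl4 25.0 ± 22.6 against 327 ± 194 (-3.86 ± 0.77, 0.179). Tubb4b (-0.57, 0.0962) and Cd36 (-1.67, 0.115) were lower, and Cfp (1.31 ± 0.20, 0.0684), Ifi27 (1.24 ± 0.22, 0.0962) and Crtc3 (1.05, 0.0962) higher. limma called 0 genes, with 2375 at unadjusted p under 0.05. Of 52 interferon-stimulated genes 36 were lower adjusted over the list alone (median -1.12; 0.476 with an estimated correlation). Also adjusted over the list alone, 10 of the disease-associated genes were higher and 1 lower (median 0.25; 0.0302), and 8 of the MHC class I and 8 of the NF-kB genes were lower (0.515 for each). The brain libraries in that fit set part of its spread. Without the pair of brain libraries whose Tbk1 goes against their labels, a fit chosen after the data were seen, 22 genes were up and 56 down, and with untreated spinal cord in place of brain, also chosen afterwards, 56 up and 105 down. Leaving out spinal cord WT 4 gave 1 gene and KO 2 gave 4, and leaving out the brain library labelled WT 2 gave 1 and that labelled KO 2 gave 4 up and 8 down. In the model with untreated spinal cord Cxcl13 rose by 2.39 ± 0.49 (adjusted p = 0.0224), to 309.5 ± 170.6 TPM from 58.4 ± 30.4. Peli1, a ubiquitin ligase of Toll-like receptor signalling, fell by 1.46 ± 0.10 (adjusted p = 6.13e-08), to 51.8 ± 5.36 from 144 ± 15.0, and Rxrg rose by 2.60 to 18.0 ± 1.60 from 2.15 ± 0.321. Of the interferon-stimulated genes 28 of 52 fell there (45 adjusted over the list alone; 0.0223 with an estimated correlation), among them Oasl1 (-3.62), Isg15 (-2.04), Ifitm3 (-1.96) and Usp18 (-1.81). There 5 of 31 disease-associated genes rose (0.0330), which were Itgax (1.17), Cst7 (0.78), Ctsd (0.56), Cd63 (0.46) and Timp2 (0.43).

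Whether TBK1 alters the response to LPS was asked by comparing LPS with untreated 4 month spinal cord, a comparison across treatments chosen after the data were seen. Differences in batch, handling or time of day between LPS and untreated mice were not tested and cannot be told apart from LPS here. In WT, Saa3 rose by 9.35 ± 0.39 (adjusted p = 7.47e-12) to 2642 ± 1671 TPM (n = 4) from 2.33 ± 0.470 (n = 5), the scavenger receptor Msr1 by 6.81 ± 0.44, the decoy receptor Il1r2 by 6.25 ± 0.51, Ccl5 by 5.94 ± 0.31, Ecm1 by 5.80 ± 0.31 and Ccl12 by 5.08 ± 0.26 to 5084 ± 2378. Cxcl10 rose by 4.76 ± 0.63, Ifitm3 by 3.85 ± 0.27, Il1b by 3.44 ± 0.25 to 75.2 ± 18.4 from 6.29 ± 2.64, and Irf7 by 3.18 ± 0.34 to 121 ± 30.6 from 14.3 ± 8.40. Upk1b fell by 3.84 ± 0.28, S1pr1 by 3.46 ± 0.27, P2ry12 by 3.13 ± 0.33 to 851 ± 586 from 6278 ± 496 and Gpr34 by 2.92 ± 0.25, together with Mycl, Gpr165 and the clock gene Dbp. Of 52 interferon-stimulated genes 48 rose (median 1.80; 0.0651 with an estimated correlation) and 23 of 23 homeostatic genes fell (0.0917). Of 36 NF-kB targets 23 rose and 4 fell (0.105). In the other lists 18 complement receptor genes rose and 4 fell (0.00221), 30 of 34 respiratory chain genes rose (0.00229), 13 MHC class I genes rose (0.121) and 24 of 36 autophagy genes fell with 1 up (0.175). In KO, Saa3 rose by 8.59 ± 0.39, Ecm1 by 6.45 ± 0.31, Msr1 by 5.26 ± 0.44, Fn1 by 5.07 ± 0.39 and Adamtsl4 by 4.72 ± 0.31. Upk1b fell by 3.83 ± 0.28, and the clock genes Dbp, Nr1d1 and Nr1d2 and the receptor Tnfrsf17 also fell. P2ry12 fell by 2.21 ± 0.33 to 1261 ± 539 from 5402 ± 218, and 20 of 23 homeostatic genes fell (0.155). Complement receptors (17 up and 1 down; 0.00101) and the respiratory chain (31 up; 0.00150) rose as in WT, but 12 interferon-stimulated genes rose and 4 fell (median 0.21; 0.603), and Irf7 was unchanged (0.23, adjusted p = 0.650). Cxcl10 fell by 1.94 ± 0.63 in KO, a call lost without 4 month KO 5 (0.0518), LPS KO 2 (0.101) or LPS KO 3 (0.084). limma called 3218 up and 5103 down in WT and 2437 up and 3523 down in KO, with 2648 and 1821 predicted or unnamed. Malat1 was 6314 TPM after LPS and 12599 untreated in WT (exact p = 0.00794, adjusted p = 0.0132), and 7722 and 12937 in KO (adjusted p = 0.0238). Genes at 1 TPM or more numbered 15888 and 16757 in WT (adjusted p = 0.0132) and 16215 and 16858 in KO (adjusted p = 0.0298). The mitochondrial share was 2.57% and 1.90% in WT (adjusted p = 0.0238) and 2.68% and 2.32% in KO (0.162), and the ribosomal share 1.17% and 0.696% in WT (0.0132) and 1.05% and 0.718% in KO (0.0238). Immediate early genes added up to 1590 TPM after LPS and 2430 untreated in WT (0.0132) and 1747 and 2553 in KO (0.0298). The median of all genes was -0.17 in WT and -0.12 in KO, and median centring moved the share that rose from 38.7% to 59.7% in WT and from 40.9% to 59.8% in KO.

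The interaction of genotype with LPS called 6 genes up and 95 down. The response of Cxcl10 was lower in KO by 6.71 ± 0.88 log2 units (adjusted p = 0.00124), with 22.3 ± 21.8 TPM after LPS and 67.7 ± 26.8 untreated in KO, and 232 ± 142 and 6.55 ± 3.73 in WT. Oasl1, an antiviral gene, was lower by 4.42 ± 0.61, with 2.58 ± 1.66 after LPS in KO and 46.3 ± 24.6 in WT, and Cd69 by 3.71 ± 0.56, with 8.63 ± 1.97 and 31.4 ± 19.8. Ifi27 was higher by 1.33 ± 0.17, since LPS left it at 99.7 in KO and lowered it to 41.8 ± 3.89 from 94.5 ± 8.78 in WT, and Ecscr was higher by 0.70 ± 0.13. Of 52 interferon-stimulated genes 28 had a lower response in KO (40 adjusted over the list alone; median -1.54; 0.00526 with an estimated correlation), including Irf7 (-2.95) and Zbp1 (-2.45). Of 36 NF-kB targets and cytokines 9 had a lower response (17 adjusted over the list alone; median -0.85; 0.00526). Ccl4 was at -3.30, Ccl2 at -3.23, Ccl5 at -3.15 and Il1b at -1.70. Of the MHC class I genes 4 had a lower response (16 adjusted over the list alone; median -0.58; 0.00526). Homeostatic genes had 1 call (median 0.36; 0.319). Il12b (-3.88 ± 0.84), Ccl7 (-3.70 ± 0.81), Ccser2 (1.08), Ccl6 (0.78) and Ypel5 (0.70) lost their calls without any of 13, 14, 15, 14 and 11 libraries, with adjusted p then between 0.0501 and 0.126. Untreated KO were already higher than WT in Cxcl10, Cd69, Ccl5 and Ccl2, which lowers a response measured from that baseline. The same limit holds for the lists. Untreated at 4 months (mm10), the median genotype changes of interferon-stimulated, NF-kB and MHC class I genes were 0.34, 0.37 and 0.25. In LPS spinal cord, from the 16 library fit, they were -1.12, -0.33 and -0.15. Leaving out LPS WT 1 gave 163 calls, LPS KO 3 gave 170 and LPS WT 3 gave 59, and with the brain libraries in the model 1 gene was higher and 21 lower.

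**Figure D4:**
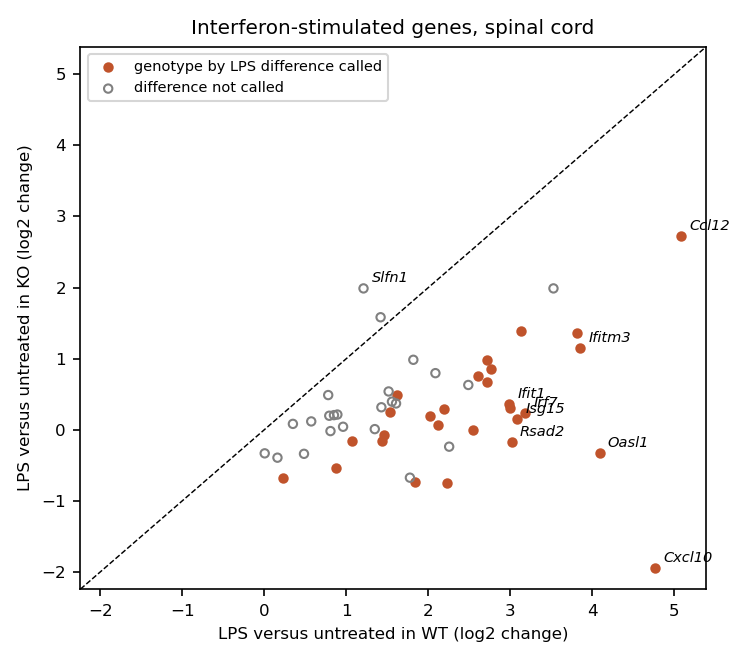
Log2 change from untreated to LPS spinal cord for 52 interferon-stimulated genes, WT on the x axis and KO on the y axis, with equality dashed and the 28 genes called in the interaction filled. The change is larger in WT for 50 of 52 genes, with medians of 1.80 in WT and 0.21 in KO.

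In LPS treated brain, whose libraries labelled WT 2 and KO 2 have Tbk1 levels opposite to their labels, limma called 0 of 19404 genes between KO and WT, with 617 at unadjusted p under 0.05 and a smallest adjusted p of 0.238. As labelled, 24 of 31 disease-associated genes were positive (median 0.0898, adjusted p = 0.0476 with an estimated correlation), and interferon-stimulated genes had a median of -0.50 (0.792). Cxcl13 was 223 ± 160.5 TPM in KO (n = 4) and 36.5 ± 30.5 in WT (n = 4), Axl 77.8 ± 20.6 and 42.6 ± 5.33, and Cxcl10 105 ± 142 and 140.0 ± 108. Lox (1.58) had a small unadjusted p among higher genes, and Erdr1y (-2.17), Snord55 (-2.12) and Gng5c (-0.51) among lower ones, all at an adjusted p of 1.00. Without the libraries labelled WT 2 and KO 2, which leaves 3 per group and was chosen after seeing them, 2 genes rose, Rxrg (2.74 ± 0.19, to 24.2 ± 3.14 from 2.83 ± 1.01) and Cxcl13 (3.58), and 5 fell, Peli1 (-1.25), Irf7 (-1.88), Parp14 (-0.84), Ube2l6 (-1.14) and Tbk1 (-1.69). Then 45 of 52 interferon-stimulated genes were lower adjusted over the list alone (median -1.14; 0.0310 with an estimated correlation). Leaving out brain WT 1, WT 4 or KO 4 alone gave 1 gene each, and leaving out spinal cord WT 1 gave 2.

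Spinal cord and brain of LPS treated mice were compared within genotype, as labelled. The titles give the brain libraries 22 months and the cord libraries 4 months, against 4 months for both in the design text, so tissue differences would also hold an age difference if the titles were right. In WT, Spp1 was higher in cord by 3.21 ± 0.46 (486 ± 93.0 TPM, n = 4, against 55.9 ± 23.2, n = 4), Apol7d by 2.93 ± 0.38, the matrix gene Fn1 by 2.73 ± 0.42, Cd36 by 1.95 ± 0.31, Axl by 1.76 ± 0.18 (148 ± 24.9 against 42.6 ± 5.33), Slc2a6 by 1.61 ± 0.25 and Cd72 by 1.48 ± 0.29, with Cxcl14 (1.67) and Spon1. Siglec1 (1.67 ± 0.44) lost its call without brain WT 2 (0.0508). Brain was higher in Sap25 (-3.55 ± 0.53), Slfn4 (-2.83 ± 0.33), Ifitm1 (-2.32 ± 0.33, 126 ± 50.3 in brain against 24.1 ± 8.45), Gadd45g (-2.33), S100a9 (-2.08), Apoe (-1.28) and Il1b (152 ± 36.7 against 75.2 ± 18.4), and also in Erdr1x, H2ac19, H2-K2, Stfa2l1 and Srsf5. Anxa1 (-2.32) lost its call without any of 7 libraries (0.0502 to 0.0709). Of 31 disease-associated genes 4 were higher in cord and 2 lower (median 0.11; 0.00402 with an estimated correlation). Neutrophil genes were lower in 8 of 13 (10 adjusted over the list alone; 0.564), immediate early genes in 13 of 25 with 1 higher (0.357) and autophagy genes in 14 of 36 (18 adjusted over the list alone; 0.564). Ribosomal genes were higher in 15 and lower in 3 (0.226), and 7 of 34 respiratory chain genes (0.110) and 7 of 21 cholesterol genes (0.161) were higher. Of 7 myelin genes 4 were higher and 1 lower (0.0600). Neutrophil genes added up to 1534 TPM in cord and 5152 in brain, and Malat1 was 6314 and 16356 (exact p = 0.0286 and adjusted p = 0.0536 for both).

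In KO, Fn1 (2.79 ± 0.42), Apol7d (2.53 ± 0.38), Spp1 (2.43 ± 0.46, 174 ± 95.4 TPM, n = 4, against 36.9 ± 33.6, n = 4) and Axl (1.37 ± 0.18) were again higher in cord, with Htra3 (1.37), Mcub (1.38), Bhlhe40 (1.35) and Cyp4f18 (1.34), and H2-K2, Slfn4, Srsf5, Eif4a2, Syne4, Ptbp2, Ccdc66 and Rpl10 were lower. Pdcd1 (1.61) lost its call without cord KO 2 (0.053) or brain KO 3 (0.0521), and H2-Eb1 (-1.63) without cord KO 2 (0.0642) or KO 4 (0.0518). Disease-associated genes had 9 higher and 1 lower of 31 (median 0.24; 9.8e-05), complement receptors 1 higher (0.0212), and NF-kB targets 10 lower (16 adjusted over the list alone; median -0.71; 0.397). limma called 563 genes higher and 3842 lower in WT, and 195 and 1543 in KO, with 1326 and 399 predicted or unnamed. When only the KO groups were fitted, 10 genes were called in KO. With the replicate number as a block, 66 named genes lost their call in KO, which was all that had been called. Whether the numbers mark shared mice stays open. The direction of the tissue calls depended on scaling. The median of all genes was -0.25 in WT and -0.21 in KO. After quantile normalization the share that was higher went from 12.8% to 47.9% in WT (1103 and 1198 genes) and from 11.2% to 52.6% in KO (245 and 221). After median centring it went to 70.6% and 76.6%. In WT, leaving out brain WT 1 gave 2874 calls and brain WT 2 gave 2748. In KO, leaving out cord KO 1 gave 2932, cord KO 2 gave 349, cord KO 4 gave 916, brain KO 1 gave 933, brain KO 2 gave 674 and brain KO 3 gave 425. Median, mean and test differed in sign for homeostatic, MHC class II, lipid efflux and T and NK lists in both genotypes, for NF-kB, TBK1 pathway and TGF-beta in WT, and for MHC class I, glycolysis and monocytes in KO. The interaction of genotype with tissue called 0 genes by limma, with 1062 at unadjusted p under 0.05 and a smallest adjusted p of 0.299. Cfp (1.33), Crtc3 (1.15) and Galt (0.81) had the smallest unadjusted p among named genes higher in KO cord, and Spon1 (-2.18), Rras (-0.70) and Tubb4b (-0.56) among those lower. Leaving out cord WT 1, brain WT 4 or brain KO 4 gave 1 gene each.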

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

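The tests of exchanged labels, of incomplete deletion and of a short copied stretch beside Cx3cr1, its LPS values included, were chosen only after the results were seen, as were the comparisons of LPS with untreated mice.

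The brain libraries labelled WT 2 and KO 2 carried the expression of the other genotype. That labelled KO 2 stood apart from the other KO in Tbk1 (55.0 TPM), Irf7 (139), Cxcl10 (318), Oasl1 (42.4), Ccl4 (245), Peli1 (211) and Spp1 (86.9), and that labelled WT 2 stood apart in Rxrg (15.6). On a score of 100 genes that separate LPS spinal cord KO from WT, the library labelled KO 2 was at -2.49 where the other KO were at -0.92 to -0.68, and that labelled WT 2 at -0.55 where the other WT were at -2.43 to -1.74. Incomplete deletion in the library labelled KO 2 alone is argued against by the 18.6 TPM of Tbk1 in that labelled WT 2, and a score difference of -1.94 between them is consistent with an exchange of labels, which stays a hypothesis. The labels were kept as given, so directions drawn from LPS brain rest on them.

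The NF-kB and cytokine genes were higher as a list in 22 month KO, where neutrophil and monocyte markers had higher means that did not pass the threshold. With the marker level as a covariate the median change of 35 of these genes was 0.352, against 0.340 without it, and the p with an estimated correlation was 1.5e-06 against 7.2e-07. Single calls in the list went from 10 to 4 and all calls from 80 to 54; over those 10 the median change went from 1.08 to 1.03 and the median standard error from 0.214 to 0.241. Neutrophils and monocytes as the whole source of the pattern are therefore argued against, although the sort on CD11b and CD45 would not remove them. T cells, most of which a gate on CD11b would remove, NK cells, which may carry CD11b, and a response of microglia themselves stay open.

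Rpsa lies on chromosome 9 (120127766 to 120132369 in mm10), with its start coordinate 0.0791 Mb from that of Cx3cr1. It was higher in KO by 0.61 ± 0.07 at 4 months (limma adjusted p = 1.4e-05) and by 0.64 ± 0.07 at 22 months (4.3e-05). Within 10 Mb there were 2 calls, Rpsa and Ccrl2, among 113 genes tested, with no clear excess (Fisher's exact p = 0.331, odds ratio 1.72). A long chromosome segment carried with the Cre allele could change few of its genes. The test therefore cannot decide about such a segment, which stays open. Slc25a38, the neighbour of Rpsa, was at 0.54 ± 0.16 and 0.69 ± 0.17 (unadjusted limma p no larger than 0.00238, adjusted p of 0.155 and 0.0737). Extra copies of a short stretch could give this and stay a hypothesis. Csrnp1 (0.17) and Wdr48 (0.00) on the other side were not called at 4 months. In the fit of 18 cord libraries Slc25a38 was at 0.55 ± 0.15 untreated and 0.47 ± 0.17 after LPS. Rpsa was at 0.51 ± 0.12 untreated and 0.20 ± 0.13 after LPS (limma adjusted p after LPS of 0.213 and 0.571). Whether Rpsa differed between the treatments was not tested, so its LPS value does not decide about copies. Reads shared with pseudogenes of Rpsa and an effect of Tbk1 itself stay open.

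Other splits of the same libraries gave fewer genes than the real groups for genotype at 4 months (145 against at most 11) and at 22 months (80 against 54), ageing in WT (2920 against 293) and in KO (3399 against 2297), and the genotype by age interaction (7 against 1). The same held for tissue in WT (4405 against 2) and in KO (1738 against 7), LPS in WT (8321 against 5364) and in KO (5960 against 2936), and their interaction (101 against 61). Chance alone is argued against for the counts outside the interactions, only as far as 35 splits for tissue and 100 for each of the others can show. For the interactions with age and LPS, the splits mixed WT and KO within each age or treatment. That removes the genotype difference itself and adds it to the spread, so these splits cannot decide about chance in the interaction counts. The highest other splits for genotype at 22 months, ageing in KO and LPS kept the true groups apart but for 1 library. For genotype in LPS spinal cord and LPS brain, with 0 calls by limma (2375 and 617 at unadjusted p under 0.05), all 35 splits gave as many by construction, as did all 100 for the genotype by tissue interaction (0 by limma, 1062 unadjusted), which says nothing about chance. The highest other values were 4, 57 and 4. The 57 came from the split that exchanges the brain libraries labelled WT 2 and KO 2, which points to a structure in the brain libraries that their labels do not follow.

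Genotype effects differed between ages by the interaction test for 7 genes, Axl (-1.10), H2-Q7 (-1.30), Il2rg (-1.05), Pear1 (-0.95), Pilra (0.74), Rxrg (-1.55) and Vcam1 (-1.26). They differed between LPS and untreated spinal cord for 101 genes, among them Cxcl10 (-6.71), Oasl1 (-4.42), Il12b (-3.88), Cd69 (-3.71), Ccl7 (-3.70), Ifi27 (1.33), Ccser2 (1.08), Ccl6 (0.78), Ecscr (0.70) and Ypel5 (0.70). The interferon-stimulated, NF-kB and MHC class I lists did too, with medians of -1.54, -0.85 and -0.58. Each of these lists already had a positive median in untreated KO at 4 months, which lowers a response measured from there. Rxrg, H2-Q7, Pilra and Pear1 with age, and Il12b, Ccl7, Ccser2, Ccl6 and Ypel5 with LPS, lost their calls without some single libraries. Leaving out each library gave 3 to 10 genes with age and 59 to 170 with LPS.

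Of 304 values tested over 30 genes and 10 library measures, 30 stood apart from their group, where chance gives about 15.2 at 1 in 20. In untreated spinal cord at 4 months these were Ripk1 (53.7 TPM) and the ribosomal share (1.33%) in WT 4, Sqstm1 in KO 3 (328), Apoe (1232) and Malat1 (18091) in KO 2, Spp1 in KO 4 (74.0) and the ribosomal share in KO 1 (1.79%). At 22 months, WT 5 had the highest neutrophil (13080 TPM), monocyte (1309) and T and NK markers (63.8) and the highest Ifitm3 (656) of its group but the lowest Tnf (5.79), Gpnmb was high in WT 4 (87.5), Ifitm3 in KO 2 (785) and Axl in KO 4 (663). In LPS spinal cord Ikbke (31.9) and Vcam1 (75.0) stood apart in WT 2, Axl in KO 4 (237), Spp1 in KO 1 (317), and the neutrophil (14737) and monocyte (1090) markers in KO 3. In LPS brain the T and NK markers were low in WT 4 (24.7). No cause was tested for these values.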

How the results depend on the processing

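Fits without the doubted pair of brain libraries (those labelled WT 2 and KO 2), with protein-coding genes alone, with untreated spinal cord in place of brain or with brain added were chosen only after the results were seen.

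The increases of Cxcl13, Cxcl10 and Ccl5 and of the NF-kB and MHC class I lists in KO at 4 months kept their direction under the alternatives run. So did the loss of homeostatic genes with age. The count of genes that differed by genotype at 4 months was 145 and became 77 with replicate numbers as a block. At 22 months the 80 genes (49 up, 31 down) became 42 when only the groups compared were fitted, and 96 with the block (83 up, 13 down), 40 of them shared. The 3399 genes of ageing in KO became 1675 with the block. The 7 genes of the genotype by age interaction became 4 with a pseudocount of 5 and 3 with median centring. The numbers were not taken to pair libraries. Same-number WT and KO libraries correlated at -0.151 to 0.0535 at 4 months and 0.0245 to 0.148 at 22 months after group means were removed. LPS spinal cord and brain correlated at -0.0563 to 0.216 in WT and -0.0532 to 0.283 in KO, and 3 of 4 in each matched best with their own number, so that shared mice between tissues stay open. Across genotypes, same-number cord WT and brain KO correlated at -0.106 to 0.287, and cord KO and brain WT at 0.0430 to 0.141. In each of these 2 of 4 matched best with their own number. The cause of the changes in the counts was not tested.

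For KO against WT in LPS spinal cord, 0 genes were called as reported, 2 without a filter, 2 with a filter at TPM 5, 6 with only the groups compared, 3 with library weights, 1 over protein-coding genes, 78 without the doubted brain libraries and 161 with untreated spinal cord in place of brain. In LPS brain 0 became 7 without the doubted libraries. The genotype by tissue interaction had 1 call without a filter. Without the doubted libraries the median residual SD stayed at 0.287 over all genes and fell from 0.638 to 0.432 over 52 interferon-stimulated genes. The cause of the other changes was not tested.

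Spinal cord against brain in WT gave 4405 genes, 2301 after quantile normalization and 2586 without the doubted libraries. In KO it gave 1738, with 671 without a filter, 466 after quantile normalization, 865 after median centring, 10 with only the groups compared, 0 by limma with the block and 560 without the doubted libraries. LPS against untreated gave 8321 in WT and 5427 over protein-coding genes, of which fewer were tested, and in KO 5960 and 2386 with the block. The genotype by LPS interaction gave 101, with 39 without a filter, 161 with library weights and 22 with brain libraries added. The cause was not tested.

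Leaving out each library of the groups compared in turn gave 108 to 140 genes by genotype at 4 months, 54 to 89 at 22 months, 2370 to 2915 for ageing in WT, 2562 to 3451 for ageing in KO and 3 to 10 for their interaction. The ranges were 0 to 4 for genotype in LPS spinal cord, 0 to 1 in LPS brain and 0 to 1 for the tissue interaction. Between tissues they were 2748 to 3844 in WT and 349 to 2932 in KO. For LPS they were 7174 to 8067 in WT, 4967 to 6106 in KO and 59 to 170 for the interaction.

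Among lists compared between tissues, lipid efflux in WT (median 0.20) and homeostatic genes in KO (median 0.00546) went in the opposite direction by fry, with adjusted p of 0.988 and 0.989. After quantile normalization the medians of mitochondrially encoded genes in WT (-0.0577) and of homeostatic genes in KO (-0.10) reversed, with adjusted p of 0.369 and 0.212. The cause was not tested, and no other list reversed.

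Across genes, the correlation of genotype at 4 months with ageing in WT was 0.374, became 0.407 with a pseudocount of 0.1 and 0.108 with controls split, and ran from 0.334 to 0.430 leaving out each library. That of genotype at both ages was 0.191, became 0.116 with a pseudocount of 0.1 and 0.274 with a filter at TPM 5, and ran from 0.140 to 0.234. Genotype in LPS spinal cord and brain correlated at 0.0835, at 0.0397 with a pseudocount of 0.1, at 0.139 with a filter at TPM 5 and at 0.314 without the doubted libraries. It ran from -0.0171 to 0.221, below 0 without brain WT 3, WT 4 or KO 1. Genotype in LPS spinal cord (mm39) and untreated spinal cord (mm10), from separate models matched by gene symbol, correlated at 0.00333, with a range of -0.0204 to 0.0377.

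Of the values of named genes over the alternatives, 623 of 679 for genotype at 4 months and 426 of 475 at 22 months stayed on the side of the threshold reported. For ageing these were 1742 of 1806 in WT and 1542 of 1580 in KO, for tissue 1294 of 1400 and 658 of 930, and for LPS 1767 of 1810 and 1562 of 1627. For the interactions they were 102 of 144 with age and 162 of 240 with LPS. No named gene reversed. With the block Itgax, Madcam1, S1pr1, Masp1, C3, Il1b, Fcgr4, Gpr34 and Gbp2 were not called at 4 months, nor were Cxcl2, Ptprcap, Mpv17l, Upk1b, Chchd6, Cxcl16, Htra3, Mrc2, Gas6 and Mettl15 at 22 months. No depth was given with the TPM, so its effect could not be measured.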

Other observations

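The mm39 mapping of the untreated 4 month libraries and the comparisons of LPS with untreated spinal cord were chosen only after the results were seen.

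After LPS in WT, 10 of 15 TGF-beta signalling genes fell and 0 rose (median -0.50; adjusted p = 0.175 with an estimated correlation), and Trem2, a lipid receptor of the disease-associated state, fell by 1.49. Disease-associated genes split, with 10 up and 11 down of 31 in WT and 13 up and 11 down in KO, and Apoe did not change in WT (0.01, adjusted p = 0.984). Of the MHC class II genes 6 were lower and 1 higher, Cd74 at 2.00, and the list was not called (adjusted p = 0.373 with an estimated correlation). The C5a receptor C5ar1 rose by 2.32 and Fcgr4 by 3.88, and 45 ribosomal protein genes rose in WT and in KO alike (medians 0.80 and 0.58; 0.0651 and 0.0710).

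B cell markers added up to 252 TPM after LPS and 582 untreated in WT (exact p = 0.00794, adjusted p = 0.0132), and to 226 and 525 in KO (adjusted p = 0.0238). Border macrophage markers were 192 and 152 in WT and 172 and 106 in KO, with the same adjusted p. Endothelial markers, whose list was too small for a list test, added up to 34.5 TPM at 22 months and 19.9 at 4 months in WT (adjusted p = 0.0298), and 35.3 and 16.2 in KO (adjusted p = 0.0397). Pecam1 among them fell with age in WT and in KO. The sum therefore joins markers that moved in opposite directions and does not show more endothelial RNA with age. After LPS the sum of endothelial markers fell by 1.22 in WT, to 7.70 TPM (adjusted p = 0.0132), and by 0.95 in KO, to 7.68 from 15.7 (adjusted p = 0.0238). Astrocyte markers were 53.2 and 82.6 in WT (adjusted p = 0.0132) and 63.7 and 99.6 in KO (adjusted p = 0.0298), and myelin markers 1337 and 1955 in WT (adjusted p = 0.0132) but were not called in KO (adjusted p = 0.339). B cell markers were 479 TPM at 22 months and 614 at 4 months in WT (adjusted p = 0.0298). In the mm39 mapping of the untreated 4 month libraries 88 genes rose and 14 fell in KO, with Tbk1 at 10.3 ± 1.65 TPM in KO and 42.8 ± 4.45 in WT.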
